A study of Mus musculus with 4 samples.

How the data were processed

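Back skin of 4 wild-type C57BL/6 mice aged 8 weeks was compared, 2 unwounded mice and 2 mice whose wounds were removed after 1 day, with 1 single-nucleus RNA library per mouse. Group and replicate number were read from the sample titles. Libraries were prepared with the 10x Genomics Single Cell 3' v3.1 protocol, per the labels. The deposited values were raw UMI counts per gene and barcode that the authors made with Cell Ranger 5.0.1 against GRCm38, per the file headers and the submitters' processing notes. Whether intronic reads were counted, which annotation release was used and how barcodes were called from empty droplets are not given in the sources used here. The 4 count matrices listed the same 32285 genes, and 32235 of them matched the GENCODE vM21 annotation of GRCm38 used here by gene identifier for coordinates and gene length (start to end of the gene). No genome sequence was aligned to.

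The deposited matrices held 6965 and 9840 barcodes for unwounded replicates 1 and 2 and 4635 and 18026 for wounded replicates 1 and 2. A nucleus was kept with at least 200 genes and at most 5% mitochondrial counts, a limit set before the data were examined, as were the groups, tests, gene lists, cell type markers and the rule for named genes. Scrublet scores, computed for each library with scanpy 1.11.5, marked 0, 0, 11 (0.461%) and 0 nuclei at the automatic threshold. As this is under the 0.5% fixed as a working minimum, the nuclei of highest score were removed at 0.8% per 1000 barcodes, which took out 388, 769, 88 and 624. The nuclei kept held 8275090, 6475744, 1189262 and 1350822 UMIs. Mitochondrial counts made up 0.0267%, 0.0679%, 0.0251% and 0.0660% of them. A level of 0 in a library was read as at most 3 counts, or 0.363, 0.463, 2.52 and 2.22 CPM, and folds against a group at 0 used 3 counts over the group's summed total. UMIs were treated as molecules, so these floors and the 95% Wilson intervals cover counting error only. Samples of the same group differed by more than sampling noise, with a chi-square per gene of 11.4 between the unwounded and 1.93 between the wounded libraries, so no library was a copy of another.

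The main test was edgeR 4.0.16 (R 4.3.3): counts were summed over all nuclei of a library, genes were filtered with filterByExpr, scaled with TMM factors of 0.782, 0.731, 1.33 and 1.32, and fitted with glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. TMM scaling places fitted log2 fold changes below the ratio of raw CPM. Nuclei were not treated as replicates, and means with SD are over 2 libraries. The exact permutation test of 2 against 2 libraries cannot go below p = 0.333 and was not used. Under the rule for named genes, the text takes the 8 genes of largest rise and the 8 of largest fall among those past the threshold, with at least 20 CPM in the higher group and both wounded libraries on the same side of both unwounded ones, leaving out gene models, mitochondrial and ribosomal protein genes. It also takes up to 4 members of smallest p from each fixed list, and fewer may be used. Outside this rule, Malat1 was named after the data were seen, and Cxcl5, Ccl2, Ccl4, Ier3 and S100a8 were named in the all-nuclei text only as list members that exceeded the 99th percentile of nearly silent genes or as the only member that rose. Genes named in the closing section were also chosen after their values were seen.

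Gene lists fixed before the data were examined, 27 in all, were tested with camera in limma 3.58.1 on voom log-CPM with an inter-gene correlation of 0.01, and again with the correlation estimated from the residuals. They covered inflammatory cytokines and chemokines, NF-kappaB targets, wound keratinocyte activation, epidermal differentiation, basal keratinocyte and hemidesmosome, hair follicle stem cell, anagen hair matrix, dermal collagen matrix, matrix remodelling, glycolysis, hypoxia, oxidative phosphorylation, adipocyte lipid metabolism, type I interferon, cell cycle, immediate early genes, heat shock, endothelial activation, efferocytosis, circadian clock, glucocorticoid response, skeletal muscle contraction, neutrophil, macrophage and monocyte, T cell, mitochondrially encoded transcripts and haemoglobin. For each list the members passing over all genes and adjusted over the list alone were counted. Some members also serve as naming markers of a cell type, 6 of 16 for dermal collagen, 8 of 13 for muscle contraction and 7 of 13 for the basal list.

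Nuclei of all libraries were clustered together without integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, with 0.5 and 2 as alternatives). A cluster was named from markers fixed in advance when at least 3 markers and at least 40% of those tested lay at least 2-fold above the other clusters and no other type came close. How markers were scored was revised after the clusters had been seen, and a separate clustering of the unwounded libraries was tried and dropped because clusters of low depth carried markers of several types. A class was to be tested where each library had 25 nuclei of it, which none reached. The comparison within cell types was therefore made on wounded barcodes of at least 100 genes clustered alone (27 clusters) against the joint clusters of unwounded nuclei, for fibroblast, basal keratinocyte, skeletal muscle and sebocyte names. It and the interaction of cell type and group on these sums were added after seeing the data. The interaction was fitted with the library as a term. Values within a type therefore come from 2 clusterings with different limits on genes per barcode. Defining genes of these clusters are not given as results, and cluster sizes are not compared between groups.

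To describe counts in genes that skin does not express, the CPM of 1466 olfactory and vomeronasal receptor genes was divided by their summed length, and the length of any other gene times this density gave its length-expected CPM. The ratio's spread was read from 1891 protein-coding genes of at least 5 kb with under 0.2 CPM in both unwounded libraries. Alternatives planned in advance were DESeq2 1.42.0, RLE factors, no filter on low counts, a replicate block, thinning to the smallest library, 100 or 400 genes per nucleus, all barcodes, no mitochondrial limit, no doublet removal, other clustering resolutions and leaving out each library. Added after seeing the data were removal of a lowess trend of fold change on gene length (span 0.3), subtraction of the length-expected counts, and barcodes with a Malat1 UMI only. Counts were subtracted in the wounded libraries only, and results below 0 were set to 0. A gene below its length-expected level thus enters that fit without wounded counts, and its fold change there has no measured size. In the closing section their effect is given.

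The all-nuclei test was tested on simulated data drawn from the means and sizes of these libraries, with 17433 genes tested and 200 genes changed. It recovered 24%, 74%, 88% and 90% of 50 genes each changed 2-fold, 4-fold, 8-fold and 16-fold, with 3 false calls. The list test called the 1 changed list and 0 of 26 unchanged lists. Simulated changes were balanced between rises and falls, genes were drawn independently, and no length-dependent background was added. In the data 17629 of 20930 genes were called, so the simulation does not measure false calls there. Sums and clustering used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and igraph 0.11.9, and figures matplotlib 3.10.9. Left out were barcodes under the gene limit of the all-nuclei test, which appear in the closing section, and cell types with too few nuclei, which were not tested. A gene that met the rule for named genes is not reported here.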

Results

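Nuclear transcripts of mouse back skin were counted by single-nucleus RNA sequencing, in which each nucleus carries a barcode and each captured molecule an identifier (UMI). The skin came from wild-type C57BL/6 mice, an inbred laboratory strain, at 8 weeks of age. Intact skin from 2 mice gave the unwounded libraries, and skin with an excisional wound through its full depth, removed from 2 other mice after 1 day, gave the wounded libraries. The comparison asked which transcripts differ between wounded and intact skin in the first day of repair. The unwounded libraries held 6575 nuclei with 8275090 UMIs and 9001 nuclei with 6475744 UMIs. The wounded libraries held 2297 nuclei with 1189262 UMIs and 3706 nuclei with 1350822 UMIs. Median UMIs per nucleus were 907 and 469 in the unwounded and 360 and 303 in the wounded libraries. A count of 0 allowed a level of up to 0.363 and 0.463 CPM (counts scaled to the library total) in the unwounded and 2.52 and 2.22 CPM in the wounded libraries. These floors of 3 counts, like all intervals given, cover counting error only.

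Malat1, a long non-coding RNA kept in the nucleus, differed sharply between the groups. It made up 9.39% (95% Wilson interval 9.37 to 9.41) and 8.26% (8.24 to 8.29) of unwounded UMIs, against 0.120% (0.114 to 0.126) and 0.294% (0.285 to 0.303) of wounded UMIs. All unwounded nuclei held at least 1 Malat1 UMI, and Wilson intervals allowed up to 0.0584% and 0.0427% of nuclei without. In the wounded libraries 74.8% (73.0 to 76.5) and 60.7% (59.2 to 62.3) of nuclei had none. The 1466 olfactory and vomeronasal receptor genes, whose products serve sensory neurons of the nose, together reached 94.5 and 132 CPM in the unwounded and 7044 and 6525 CPM in the wounded libraries. Per kilobase of gene this was 0.00738 and 0.0103 CPM in unwounded skin and 0.550 and 0.510 CPM in wounded skin. Relative to the density of all autosomal protein-coding genes this was 0.00965 and 0.0138 in unwounded and 0.669 and 0.631 in wounded libraries. For genes that rose, the wounded CPM is therefore also given over the CPM that the gene's length would have at the density of the receptor genes, called observed over length-expected. This ratio was read in 1891 other protein-coding genes of at least 5 kb that were nearly silent in unwounded skin. Its median was 0.878 and 0.882 and its 99th percentile 4.97 and 5.45 in wounded replicates 1 and 2. At the density of the receptor genes, all gene lengths together would account for 68.4% and 63.4% of wounded UMIs. In the unwounded libraries the same figure was 0.918% and 1.29%. Such a background would by itself dilute RNA 3.17-fold and 2.73-fold in wounded replicates 1 and 2. For most genes that fell, observed over length-expected is not given, so their remaining wounded CPM can hold background.

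**Figure D1:**
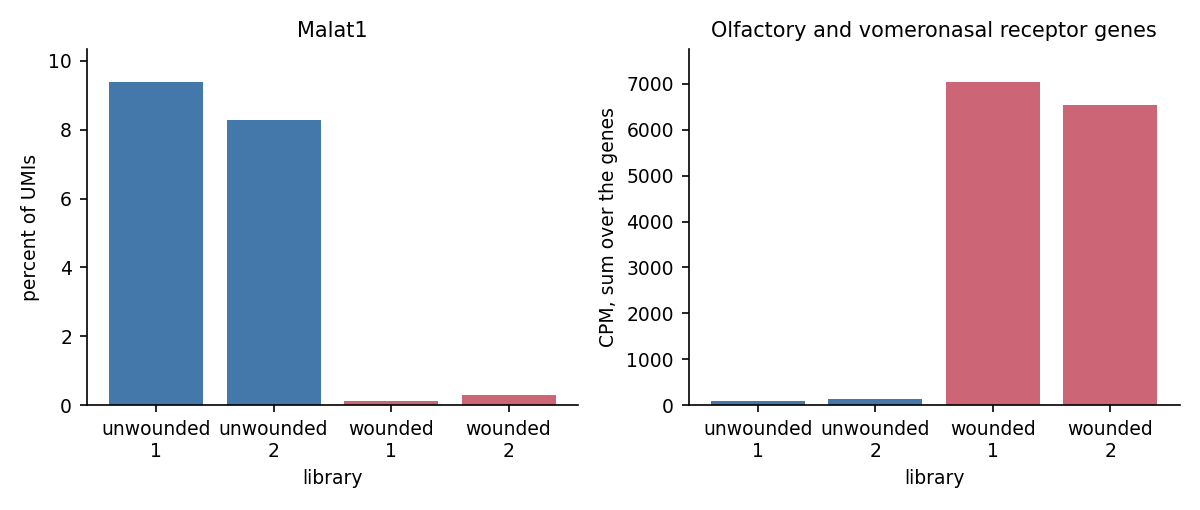
Malat1 as a percent of UMIs (left) and summed CPM of the 1466 olfactory and vomeronasal receptor genes (right), with a bar for each of the 4 libraries. Malat1 lay at 8.26% or above in both unwounded libraries and at 0.294% or below in both wounded ones, whereas the receptor genes lay at 132 CPM or below and at 6525 CPM or above.

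Chemokines and other inflammatory mediators were among the genes that rose furthest above that level after wounding. Cxcl2, which attracts neutrophils (chromosome 5, 90903871 to 90905938, GRCm38), rose from 0.198 ± 0.0617 to 32.6 ± 2.08 CPM (SD, n = 2 mice per group), a log2 fold change of 6.37 ± 0.49 (SE). Its neighbour Cxcl3 (chromosome 5, 90786103 to 90789600) had no count in unwounded skin and 43.5 ± 13.4 CPM in wounded skin, at least 214-fold higher against a floor of 3 counts over the group. Spp1, the gene of the matrix cytokine osteopontin (chromosome 5, 104435118 to 104441050), rose from 0.138 ± 0.0237 to 46.2 ± 2.48 CPM (log2 fold change 7.38 ± 0.46). S100a9, a calcium-binding alarmin of neutrophils and activated keratinocytes (chromosome 3, 90692632 to 90695721), went from 0.232 ± 0.328 to 32.5 ± 12.7 CPM (log2 fold change 6.37 ± 0.67). Krt16, a keratin of wound-edge epidermis (chromosome 11, 100246091 to 100248902), rose from 1.87 ± 1.12 to 51.0 ± 40.0 CPM, a log2 fold change of 3.94 ± 0.57. In the order Cxcl2, Cxcl3, Spp1, S100a9 and Krt16, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 7.56e-07, 1.19e-06, 1.97e-07, 7.61e-06 and 7.33e-05. Observed over length-expected was 27.3 and 32.3 for Cxcl2, 27.5 and 19.1 for Cxcl3, 14.7 in both wounded libraries for Spp1, 13.8 and 26.3 for S100a9, and 14.7 and 55.3 for Krt16.

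Several genes of dermis, muscle and epidermis fell, named here for the size of their change or a small p within a list. Col3a1, the gene of a fibrillar collagen of the dermis (chromosome 1, 45311538 to 45349706), fell from 2136 ± 303 to 62.4 ± 13.3 CPM, a log2 fold change of -5.87 ± 0.20. Ttn, which encodes the giant muscle protein titin (chromosome 2, 76703980 to 76982547), fell from 4146 ± 655 to 164 ± 17.0 CPM (log2 fold change -5.44 ± 0.19), with 0.993 and 1.24 observed over length-expected in the wounded libraries. Meg3, an imprinted non-coding RNA (chromosome 12, 109541001 to 109571726), fell from 4496 ± 45.0 to 27.1 ± 1.46 CPM, a log2 fold change of -8.16 ± 0.21. Mfap4, a protein of elastic fibres, fell from 74.7 ± 3.78 to 0.740 ± 1.05 CPM, and Krt10, a keratin of differentiating epidermis (chromosome 11, 99385254 to 99389364), fell with a log2 fold change of -5.03 ± 0.55. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment these falls had adjusted p = 1.2e-08 for Col3a1, 1.22e-08 for Ttn, 9.8e-09 for Meg3, 1.22e-07 for Mfap4 and 1.03e-05 for Krt10. Krt15, a keratin of basal and bulge keratinocytes (chromosome 11, 100131758 to 100135928), had 25.5 ± 8.24 CPM in unwounded skin and no count after wounding, at least 21.6-fold lower. The other genes of largest fall under the rule for named genes were Rbm12b2, Phf1 and Cep295nl, all without a count in wounded skin and at least 34.2-fold, 28.6-fold and 17.9-fold lower, and the transcription factor Irx2 and the creatine kinase Ckb, with log2 fold changes of -7.40 ± 0.29 and -6.95 ± 0.69.

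The 8 largest rises under the same rule all belonged to genes without a count in unwounded skin. Fgf23, a phosphate-regulating hormone (chromosome 6, 127072902 to 127081408), reached 66.7 ± 14.6 CPM, at least 328-fold higher, with 12.0 and 17.8 observed over length-expected. Cyp19a1, which encodes aromatase (chromosome 9, 54165937 to 54268110), reached 66.9 ± 0.454 CPM, at least 329-fold higher, with 1.20 and 1.28 observed over length-expected. Slc5a4b, Cpn1, Dmgdh, Tbx20 and Tex21 were at least 270-fold, 254-fold, 214-fold, 213-fold and 211-fold higher, with observed over length-expected between 1.00 (Dmgdh) and 3.65 (Cpn1). Across all genes, edgeR's test called 17629 of 20930 tested genes, of which 9819 rose and 7810 fell, and 17775 had an unadjusted p under 0.05. Of the 9819 that rose, 303 (3.09%) exceeded the 99th percentile of nearly silent genes in both wounded libraries, among them Cxcl2, Cxcl3, Spp1, S100a9 and Krt16. Another 6440 (65.6%) stayed below 2 times the length-expected CPM in both. That percentile came from genes of at least 5 kb, whereas Cxcl2, Cxcl3, S100a9 and Krt16 are shorter. The spread of the ratio among shorter genes was not measured, so for them the percentile is only a guide. The split of rises and falls differed between fits: RLE factors gave 10301 up and 7074 down, DESeq2, with its own scaling and filter, 11222 and 5816, removal of the gene length trend 8110 and 10296, and subtraction of the length-expected counts 5073 and 7455, the last 2 chosen after seeing the data. The subtraction lowered wounded counts only, with results below 0 set to 0. The median log2 fold change of all genes was 0.39 here, 0.63 with RLE factors, 1.94 with DESeq2 and -0.85 after subtraction, and changes are read against that shift.

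**Figure D2:**
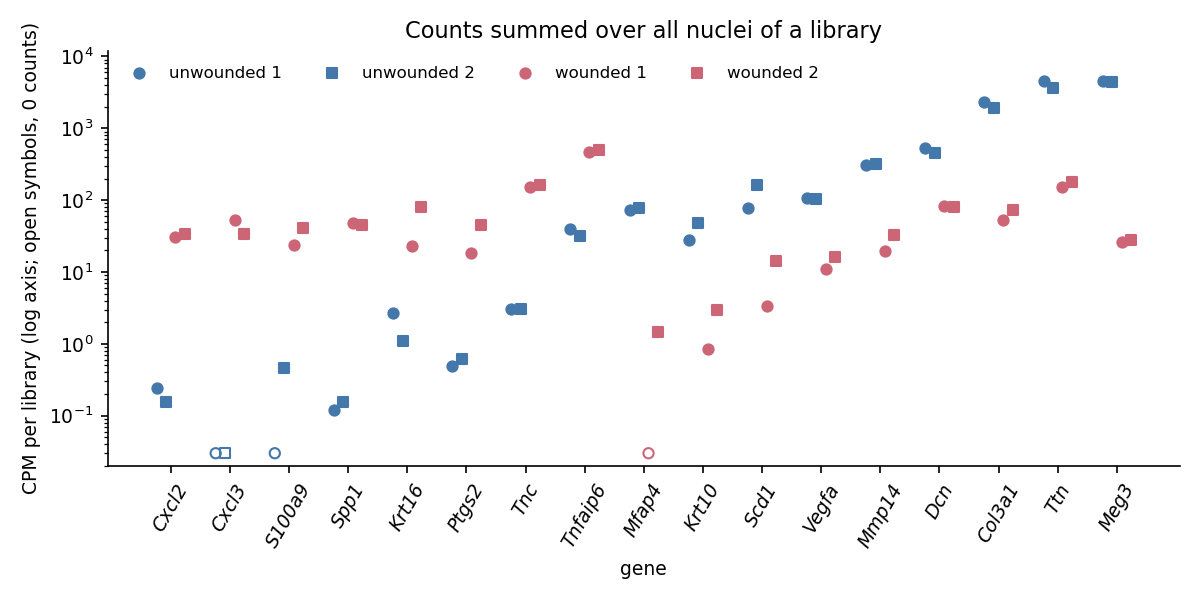
CPM on a log axis for named genes in each library, with circles for replicate 1, squares for replicate 2, blue for unwounded and red for wounded skin, and open symbols for counts of 0. Cxcl3 went from 0 to 43.5 CPM on average while Col3a1 went from 2136 to 62.4 CPM and Meg3 from 4496 to 27.1 CPM.

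Inflammatory cytokines and chemokines rose as a list fixed before the data were examined. Of 14 members measured, 10 rose, 1 fell and 3 did not pass, and adjusted over the list alone 11 rose and 1 fell. Il33, an alarmin cytokine of barrier tissue, rose from 8.48 ± 3.04 to 78.6 ± 6.52 CPM (log2 fold change 2.41 ± 0.25), with 4.25 and 4.08 observed over length-expected. Ptgs2, the inducible cyclooxygenase, rose from 0.551 ± 0.095 to 31.5 ± 18.3 CPM (log2 fold change 5.03 ± 0.56), with 4.10 and 10.6. Of the 10 members that rose, 5 (Cxcl2, Cxcl3, Cxcl5, Ccl4 and Ccl2) lay above the 99th percentile of nearly silent genes in both wounded libraries. The list's camera test gave adjusted p = 0.0399, and adjusted p = 0.460 with an estimated correlation. The call was lost without unwounded replicate 2 (0.0666), without wounded replicate 2 (0.135), after thinning to the smallest library (0.0687) and with at least 400 genes per nucleus (0.0790). NF-kappaB targets went the other way: 11 of 14 fell, 1 (Ier3) rose and 2 did not pass, with the same counts adjusted over the list alone. Nfkb1, a subunit gene of that transcription factor, fell from 227 ± 31.0 to 73.2 ± 9.56 CPM, and the adhesion molecule Icam1 from 49.9 ± 3.48 to 17.5 ± 4.55 CPM. The list's summed CPM went from 778 and 697 to 384 and 483, a smaller fall than the length-expected background could dilute RNA. That list had adjusted p = 0.00935 by camera and adjusted p = 0.460 with an estimated correlation, and it did not pass without wounded replicate 1 (0.0505), after subtraction of the length-expected counts (0.322) or in barcodes with a Malat1 UMI (0.129).

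Among leukocyte lists, T cell genes rose and macrophage genes fell as shares of the counts, and neither is read as a change in leukocytes. The 7 T cell members that rose had a median observed over length-expected of 1.36 and 1.60. T cell members rose in 7 of 8 measured cases, also adjusted over the list alone (camera adjusted p = 0.0328, adjusted p = 0.460 with an estimated correlation). Skap1, a T cell receptor adaptor, rose from 13.7 ± 0.342 to 274 ± 6.79 CPM, and Themis, needed for thymocyte selection, from 2.28 ± 0.489 to 146 ± 22.6 CPM. Their observed over length-expected was 1.72 and 1.79 for Skap1 and 1.36 and 1.18 for Themis, and none of the 7 T cell members that rose exceeded the 99th percentile of nearly silent genes in both libraries. The T cell call was lost without unwounded replicate 2 (0.0576), after thinning (0.0814) and after removal of the length trend (0.0502). Macrophage and monocyte genes fell in 10 of 11 cases, also adjusted over the list alone (camera adjusted p = 0.00935, adjusted p = 0.460 with an estimated correlation). The mannose receptor Mrc1 fell from 174 ± 10.1 to 86.1 ± 6.63 CPM, and the transglutaminase gene F13a1 from 213 ± 7.96 to 153 ± 8.49 CPM. The list's summed CPM went from 544 and 595 to 391 and 373, a smaller fall than the length-expected background could dilute RNA. The macrophage call was lost without wounded replicate 1 (0.0505) or 2 (0.0749), after thinning (0.0627) and after subtraction (0.0660). Neutrophil genes rose in 8 of 10 cases and 1 fell, the same adjusted over the list alone, and the list did not pass by camera (adjusted p = 0.0792). With fry, which tests a list against no change and not against the other genes, adjusted p was 0.0344. Csf3r, the receptor of granulocyte colony-stimulating factor, rose from 7.38 ± 2.23 to 77.2 ± 0.261 CPM (7.07 and 7.59 observed over length-expected), while the decoy receptor Il1r2 fell from 69.0 ± 7.37 to 29.8 ± 5.46 CPM. Haemoglobin and erythroid genes rose in 3 of 4 cases, also adjusted over the list alone, with camera adjusted p = 0.326 for the list (0.0126 with fry). The 3 had a median observed over length-expected of 1.32 and 1.25, and none exceeded the 99th percentile of nearly silent genes in both libraries. The globin gene Hba-a2 was not among them, so the rise is not read as more blood.

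Structural transcripts of dermis, muscle and fat fell together. Dermal collagen matrix members fell in 14 of 16 cases and 2 rose, skeletal muscle contraction members fell in 13 of 13, and adipocyte lipid metabolism members fell in 14 of 16 with 2 not passing. These counts were the same adjusted over the list alone, and camera gave adjusted p = 0.000145 for collagen, 0.000145 for muscle and 0.00301 for the adipocyte list. All 3 had adjusted p = 0.460 with an estimated correlation, and the adipocyte call was also lost after subtraction (0.322). The summed CPM of the collagen list was 13153 and 13354 in unwounded and 1106 and 1275 in wounded libraries. That of the adipocyte list was 926 and 1087 in unwounded and 809 and 737 in wounded libraries. This adipocyte fall was smaller than the length-expected background could dilute RNA. Col5a1, a minor fibrillar collagen, fell from 384 ± 12.0 to 60.1 ± 4.06 CPM, and the small proteoglycan gene Dcn from 492 ± 50.5 to 81.9 ± 0.687 CPM. The wounded level of Col5a1, a long gene, lay below its length-expected CPM, so what remained is not read as expression. Tnnt3, the fast troponin T, fell from 229 ± 22.1 to 8.70 ± 0.782 CPM. Fasn and Scd1, enzymes that make and desaturate fatty acids, fell from 34.2 ± 7.14 to 3.11 ± 0.834 and from 120 ± 59.4 to 8.71 ± 7.57 CPM. Malat1, given for the same libraries above, fell alongside each of these lists.

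Epidermal and follicular lists moved in part. Wound keratinocyte activation genes rose in 11 of 16 cases and 4 fell (12 and 4 adjusted over the list alone). The list did not pass by camera (adjusted p = 0.251), except in barcodes with a Malat1 UMI (0.0316). Tested against no change with fry, it passed (adjusted p = 0.0221). Of the 11 that rose, S100a9, S100a8 and Krt16 exceeded the 99th percentile of nearly silent genes in both wounded libraries. Lamb3, a laminin subunit, rose with 0.898 and 0.939 observed over length-expected and a log2 fold change of 2.43 ± 0.23. Subtraction of the length-expected counts set its wounded counts to 0, so the fitted -7.89 there is not a measured fall. Epidermal differentiation genes fell in 9 of 18 cases and rose in 4 (adjusted p = 0.292), basal keratinocyte and hemidesmosome genes fell in 5 of 13 and rose in 4 (adjusted p = 0.292), and anagen hair matrix genes rose in 4 of 6 and fell in 1 (adjusted p = 0.292). Adjusted over the list alone, the anagen count was 5 and 1 and the others were the same. Epidermal differentiation passed without unwounded replicate 1 (0.0269), the basal list with the length trend removed (0.0356) and the anagen list with fry (0.0244). Hair follicle stem cell genes fell in 9 of 12 cases and rose in 3, the same adjusted over the list alone, with camera adjusted p = 0.0260, adjusted p = 0.460 with an estimated correlation and 0.0687 after thinning. Cd34, a surface marker of bulge stem cells that also marks dermal and endothelial cells, fell from 137 ± 28.2 to 14.9 ± 2.00 CPM, and the repressor Tcf7l1 from 420 ± 51.2 to 112 ± 4.51 CPM.

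Matrix remodelling genes went both ways, with 7 of 19 rising and 8 falling, also adjusted over the list alone. The hyaluronan-binding Tnfaip6 rose from 35.9 ± 5.32 to 484 ± 30.5 CPM (45.0 and 53.1 observed over length-expected), and tenascin C, encoded by Tnc, from 3.05 ± 0.0476 to 158 ± 5.31 CPM (3.21 and 3.63). Mmp14, a membrane-bound collagenase (chromosome 14, 54431612 to 54445364), fell with a log2 fold change of -4.36 ± 0.21. The list did not pass (adjusted p = 0.641), and its camera direction was down while its median and mean fitted log2 fold changes were 0.18 and 0.26. Endothelial activation genes rose in 7 of 11 cases and fell in 2 (adjusted p = 0.482), the same adjusted over the list alone, and none of the 7 exceeded the 99th percentile of nearly silent genes. Cell cycle genes rose in 12 of 18 cases and 1 fell, the same adjusted over the list alone (adjusted p = 0.0632), with a median observed over length-expected of 1.33 and 1.46 among the 12. The cell cycle list passed with fry (0.00903), after thinning (0.0371) and in barcodes with a Malat1 UMI (0.0442), and the endothelial list with fry (0.0221). With the length trend removed 5 cell cycle members rose and 3 fell, and camera's direction was down (adjusted p = 0.987). After subtraction 6 of 13 measured members rose and 2 fell (camera adjusted p = 0.355). Efferocytosis genes fell in 11 of 17 cases and rose in 5, the same adjusted over the list alone, with camera adjusted p = 0.0317 and adjusted p = 0.460 with an estimated correlation. The lipid exporter Abca1 fell from 310 ± 26.9 to 58.2 ± 6.90 CPM and Gas6, a bridging ligand for dying cells, from 144 ± 23.0 to 20.3 ± 3.74 CPM. The efferocytosis call was lost without wounded replicate 1 (0.0505) or 2 (0.0670), after thinning (0.0627), with at least 400 genes per nucleus (0.0790), with the length trend removed (0.0698), after subtraction (0.216) and in barcodes with a Malat1 UMI (0.129).

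Transcripts of respiration, oxygen sensing and the clock also fell as shares of the counts. Summed CPM went from 515 and 506 to 212 and 245 for oxidative phosphorylation. It went from 717 and 720 to 294 and 346 for hypoxia, and from 1014 and 970 to 462 and 442 for the clock. These falls were smaller than the length-expected background could dilute RNA. The same held for all other lists called as falling except dermal collagen and muscle contraction. As sums also hold background, they do not tell dilution from lower expression. Nuclear-encoded oxidative phosphorylation genes fell in 17 of 19 cases, among them Atp5c1, an ATP synthase subunit, from 47.9 ± 0.658 to 10.3 ± 0.924 CPM, and Sdha of succinate dehydrogenase, from 53.9 ± 3.35 to 18.1 ± 0.518 CPM. Hypoxia response genes fell in 11 of 15 cases and rose in 2, with the angiogenic growth factor Vegfa (chromosome 17, 46016993 to 46032369) going from 106 ± 0.299 to 13.6 ± 3.79 CPM and the histone demethylase Kdm3a from 148 ± 2.88 to 31.0 ± 2.22 CPM. Circadian clock genes fell in 11 of 15 cases and rose in 3 (12 and 3 adjusted over the list alone), with Clock going from 213 ± 1.25 to 58.6 ± 0.851 CPM and the repressor Nr1d2 from 122 ± 8.78 to 15.6 ± 5.30 CPM. Heat shock genes fell in 8 of 9 cases, and the co-chaperone Dnaja1 had a log2 fold change of -2.62 ± 0.25. Camera gave adjusted p = 0.000145 for oxidative phosphorylation, 0.0113 for hypoxia, 0.00975 for the clock and 0.00975 for heat shock, and each had adjusted p = 0.460 with an estimated correlation. Immediate early genes fell in 10 of 17 cases and rose in 1 (Klf4 from 49.8 ± 9.26 to 7.91 ± 0.711 CPM), with adjusted p = 0.0316 by camera and adjusted p = 0.496 with an estimated correlation. Glucocorticoid response genes fell in 7 of 11 and rose in 1 (Klf9 with a log2 fold change of -2.88 ± 0.20), with adjusted p = 0.0316 by camera and adjusted p = 0.588 with an estimated correlation. Hypoxia was lost without wounded replicate 1 (0.0505) and after subtraction (0.322). Heat shock was lost without wounded replicate 1 (0.0698) or 2 (0.0971), with the length trend removed (0.0502), after subtraction (0.216) and in barcodes with a Malat1 UMI (0.0984). Immediate early genes were lost without unwounded replicate 1 (0.0850) or wounded replicate 1 (0.219) or 2 (0.103), with fry (0.0616), after thinning (0.0571), with the length trend removed (0.131), after subtraction (0.623) and in barcodes with a Malat1 UMI (0.214). Glucocorticoid response was lost without unwounded replicate 1 (0.0679) or wounded replicate 1 (0.0767) or 2 (0.0637), with fry (0.0814), after thinning (0.0627), with the length trend removed (0.0914), after subtraction (0.382) and in barcodes with a Malat1 UMI (0.153). Glycolysis genes rose in 5 and fell in 6 of 15 cases (adjusted p = 0.346). Mitochondrially encoded transcripts, a sign of cytoplasmic RNA, fell in 4 of 12 and rose in none (adjusted p = 0.251), with 1 fall adjusted over the list alone. Their median log2 fold change was -0.66, and -1.53 without unwounded replicate 1. With the length trend removed 6 of 12 rose and none fell, and after subtraction 1 of 13 rose and none fell (camera adjusted p = 0.254 and 0.322). Type I interferon genes rose in 3 and fell in 6 of 15 cases (2 and 6 adjusted over the list alone; adjusted p = 0.251), where Oasl2 rose from 16.4 ± 1.77 to 66.2 ± 15.2 CPM, a log2 fold change of 1.23 ± 0.22 that was -0.0017 with the gene length trend removed. The counts of the remaining lists were the same adjusted over the list alone.

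Clustering the 4 libraries together placed wounded and unwounded nuclei apart. Of the unwounded nuclei, 5800 (88.2%) and 5915 (65.7%) fell in clusters named from fixed markers, against 4 (0.174%) and 12 (0.324%) of the wounded nuclei. Nearly all wounded nuclei lay in clusters 2 and 3, whose leading genes were the repeat-like gene models Gm10801, Gm10800 and Gm21738, and which stayed unnamed. No class reached 25 nuclei in every library, so the planned tests within classes could not be made, and changes in class shares are not read because the clusters followed the groups. With at least 100 genes per barcode the skeletal muscle class could be tested, and edgeR's test called 747 of 3748 genes (422 up, 325 down), which became 0 without unwounded replicate 1 or 2 and 552 without wounded replicate 2.

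Comparisons within cell types were added after seeing these clusters, with wounded barcodes of at least 100 genes clustered alone and set against the joint clusters of unwounded nuclei. Basal keratinocyte-like nuclei formed cluster 7 of the joint clustering (350 and 499 unwounded nuclei) and cluster 5 of the wounded clustering (202 and 734 nuclei). In them Krt16 rose from 22.2 ± 31.5 to 726 ± 9.80 CPM, a log2 fold change of 5.13 ± 0.46. Krt6b (chromosome 15, 101676023 to 101680287) had no count in unwounded nuclei and 79.2 ± 2.09 CPM in wounded ones, at least 18.4-fold higher, and Krt6a (chromosome 15, 101689910 to 101694307) rose from 5.78 ± 0.773 to 69.5 ± 15.8 CPM. Krt6a and Krt6b are wound-induced keratins and near-identical copies, so reads could have been assigned to either. The growth factor Tgfa rose from 27.5 ± 16.6 to 151 ± 33.3 CPM (8.13 and 4.40 observed over length-expected), and Spp1 from no count to 88.9 ± 11.6 CPM, at least 20.7-fold higher. Spp1 was no lower in the unnamed wounded clusters 2 (188 and 109 CPM) and 6 (210 and 144 CPM), so its counts here are not assigned to keratinocytes, and the share of free RNA was not measured. Some genes of terminal differentiation fell, with Krt10 going from 269 ± 0.456 to 13.1 ± 8.98 CPM, Krt77 from 364 ± 8.21 to 32.9 ± 8.46 CPM, Flg2 from 214 ± 50.9 to 3.36 ± 4.75 CPM, and Krt1 from 125 ± 2.51 CPM to no count, at least 8.33-fold lower. The desmosomal cadherin Dsc1, of the same list, rose from 60.7 ± 8.11 to 279 ± 71.9 CPM. The suprabasal joint cluster 6 (416 and 819 unwounded nuclei) was left out of this comparison. Wounded cluster 5 was the only wounded cluster with a keratinocyte name, and the suprabasal marker Dsg1a was among its leading genes. Changes of differentiation genes may thus reflect which nuclei were compared. Of 12 measured epidermal differentiation genes 3 rose, 5 fell (6 adjusted over the list alone) and 4 did not pass, and the list did not pass (camera adjusted p = 0.492, adjusted p = 0.961 with an estimated correlation), its summed CPM being 1949 and 2129 in unwounded and 2758 and 1371 in wounded nuclei. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, adjusted p was 2.87e-11 for Krt16, 3.31e-07 for Krt6b, 2.42e-05 for Krt6a, 7.02e-07 for Krt10 and 4.11e-06 for Dsc1, and DESeq2 did not call Krt16 (adjusted p = 0.0879).

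In these keratinocyte-like nuclei, wound keratinocyte activation was the list that rose. Of its 7 measured members 6 rose, also adjusted over the list alone, with camera adjusted p = 0.0356 and adjusted p = 0.842 with an estimated correlation. Dermal collagen genes fell in 5 of 10 cases, also adjusted over the list alone (adjusted p = 0.0356 by camera, adjusted p = 0.842 with an estimated correlation). With fry neither list passed (adjusted p = 0.0739 and 0.162). In the collagen list Col1a1 fell from 1573 ± 652 to 49.7 ± 15.3 CPM. Fibroblasts are the main source of Col1a1. In the unwounded keratinocyte-like nuclei the collagen list summed to 4600 and 6538 CPM, against 4275 and 4191 CPM for the basal keratinocyte list. Its fall is therefore not read as a change in keratinocytes. Of the 8 largest rises under the rule for named genes, the non-coding Halr1 and the myeloid receptor Trem3 were at least 67.3-fold and 61.8-fold higher, with 122 and 59.0 and with 118 and 45.5 observed over length-expected. The other 6 (Kcnh8, Cngb3, Rims2, Dnah11, Klhl32 and Spock1) had between 0.880 and 2.68. Besides Krt1, the largest falls were Meg3, from 2260 ± 440 to 3.36 ± 4.75 CPM, and Skint7, Alox12e, Srsf1, Lmo4, Plekhn1 and Marveld1, all without a count in wounded nuclei. Of 25 lists, 23 did not pass, 1 list passed without wounded replicate 1 and 3 without wounded replicate 2, and 8 of the 19 epidermal differentiation genes were among the markers used for suprabasal names. In all, 2604 of 5488 genes changed, 1503 up and 1101 down, against 2212 up and 951 down with DESeq2, 844 up and 1026 down after subtraction, and 1073 genes without wounded replicate 2.

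Fibroblast-like nuclei were compared by cluster number, joint clusters 0, 4 and 8 against wounded clusters 3, 8 and 9, because a mural marker, Pdgfrb, led in the wounded ones. The wounded clusters had 7, 5 and 6 of 8 fibroblast markers raised, but their identity is weak, as Col1a1 hardly set them apart: it had 191 and 230, 103 and 232, and 162 and 152 CPM in them, and 216 and 64.9 CPM in the unnamed cluster 11. The neutrophil chemoattractant Cxcl5 (chromosome 5, 90759360 to 90761624) went from no count to 134 ± 2.34 CPM, at least 370-fold higher, and Cxcl3 from no count to 66.2 ± 10.7 CPM, at least 182-fold higher. Il33 rose from 9.94 ± 5.18 to 418 ± 216 CPM (log2 fold change 4.82 ± 0.31), and Ptgs2 (chromosome 1, 150100031 to 150108227) with a log2 fold change of 7.25 ± 0.66. Cxcl3, Ptgs2 and Spp1 reached similar or higher levels in unnamed wounded clusters and are not assigned to fibroblasts. Nfkbia, the inhibitor that NF-kappaB itself induces, rose from 25.1 ± 4.87 to 115 ± 2.98 CPM and the early-response gene Ier3 from 4.62 ± 0.124 to 46.5 ± 17.1 CPM. Mfap4 went from 75.3 ± 0.536 CPM to no count, at least 15.8-fold lower, Mmp14 fell from 440 ± 30.2 to 77.8 ± 12.7 CPM, and Col5a1 (chromosome 2, 27886425 to 28039514) from 536 ± 2.59 to 111 ± 44.4 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 5.21e-20 for Cxcl5, 1.31e-14 for Cxcl3, 1.6e-19 for Il33, 5.66e-14 for Ptgs2, 4.33e-07 for Nfkbia, 2.12e-07 for Ier3, 1.55e-12 for Mmp14 and 9.93e-12 for Col5a1. Besides Mfap4, the largest falls under the rule for named genes included B3gat3, Cercam, Ap1s2, Snhg18, Wdr81 and Izumo4, all without a count in wounded nuclei and at least 5.02-fold (Izumo4) to 9.64-fold (B3gat3) lower. The largest rises were Cxcl5, Cxcl3, Trem3 and Spp1, the latter 2 at least 864-fold and 225-fold higher, and Tmc5, Lrriq1 and Impg1, at least 180-fold, 165-fold and 162-fold higher with 0.892 to 3.54 observed over length-expected. Fgf23, also among them, led wounded clusters 8 and 9 and is not counted as a result. Observed over length-expected was 256 and 181 for Cxcl5, 69.9 and 22.4 for Il33, 26.2 and 25.9 for Ptgs2 and 152 and 109 for Nfkbia.

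Of 26 lists, 7 passed in the fibroblast-like clusters, 4 up and 3 down. Inflammatory cytokines rose in 8 of 9 cases and 1 fell (camera adjusted p = 0.00146), wound keratinocyte activation genes rose in 8 of 9 and 1 fell (0.0468), cell cycle genes rose in 9 of 9 (0.00148), and T cell genes rose in 5 of 6 (0.0330). Dermal collagen genes fell in 12 of 15 cases and 1 rose (adjusted p = 0.000645), 6 of the list's 16 genes being fibroblast naming markers. Oxidative phosphorylation genes fell in 12 of 17 (0.0228), and clock genes fell in 8 of 12 and rose in 2 (0.0468). With an estimated correlation adjusted p = 0.589 for T cell genes and adjusted p = 0.521 for the other 6, and 2 lists passed without unwounded replicate 1, 2 without unwounded replicate 2, 4 without wounded replicate 1 and 5 without wounded replicate 2. After subtraction the calls of T cell (adjusted p = 0.0565), oxidative phosphorylation (0.0858) and clock genes (0.0858) were lost, the latter 2 also with the length trend removed (0.265 and 0.0701). Mitochondrially encoded transcripts, a sign of cytoplasmic RNA, rose in 8 of 12 cases and fell in none, against the direction in all nuclei, and did not pass in camera (adjusted p = 0.0955) but did after subtraction (0.00184) and with the length trend removed (0.000762). Adjusted over the list alone the counts were the same except for 13 falls in oxidative phosphorylation. The formin Diaph3 rose from 15.7 ± 0.913 to 146 ± 12.1 CPM with 1.24 and 0.960 observed over length-expected, and its log2 fold change of 2.76 ± 0.28 turned to -0.52 after subtraction, whereas the kinetochore gene Knl1 (3.67 and 2.66) and the spindle motor Kif11 (3.77 and 3.27) rose with log2 fold changes of 3.89 ± 0.51 and 3.52 ± 0.51. Clock fell from 246 ± 3.18 to 49.4 ± 13.5 CPM. NF-kappaB targets rose in 4 and fell in 4 of 14 cases (adjusted p = 0.898), with Nfkb1 going from 235 ± 25.3 to 60.2 ± 64.2 CPM, a fall that DESeq2 did not call (adjusted p = 0.0707). In all, 8931 of 13501 genes changed, 4220 up and 4711 down, against 5283 up and 2596 down with DESeq2, and 5811 and 5207 genes without unwounded replicate 1 and wounded replicate 2.

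**Figure D3:**
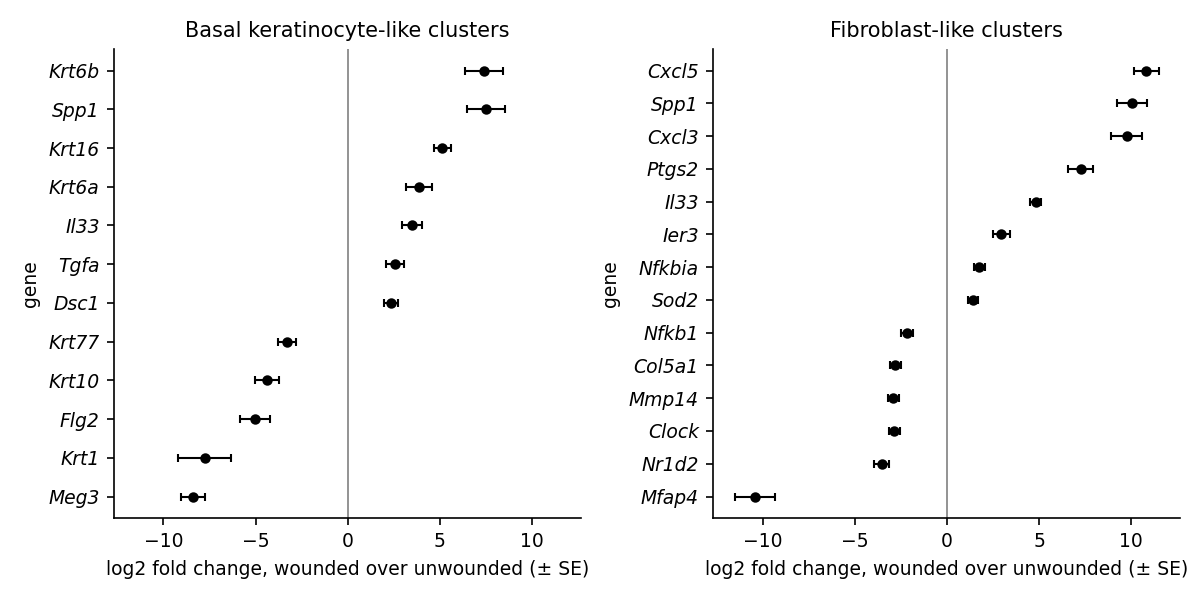
Fitted log2 fold change (wounded against unwounded) with its SE for named genes in keratinocyte-like clusters (left) and fibroblast-like clusters (right), where fitted values of genes at 0 in a group depend on the prior count. Krt16 lay at 5.13 and Krt10 at -4.41 in keratinocyte-like nuclei, and Il33 at 4.82 and Col5a1 at -2.81 in fibroblast-like nuclei.

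Skeletal muscle-like nuclei (joint cluster 10, wounded cluster 10) lost transcripts of the contractile apparatus. Tnnt3 fell from 1535 ± 398 to 122 ± 59.8 CPM, a log2 fold change of -4.08 ± 0.44 (adjusted p = 6.61e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Casq1, the calcium store protein of the sarcoplasmic reticulum, went from 317 ± 20.6 CPM to no count, at least 10.6-fold lower. Contraction genes fell in 11 of 13 cases and 1 rose, also adjusted over the list alone (camera adjusted p = 0.000448, adjusted p = 0.587 with an estimated correlation), 8 of the 13 being naming markers. The stress-induced factor Atf3 rose from 36.4 ± 44.0 to 374 ± 181 CPM (20.6 and 28.6 observed over length-expected), a call lost with DESeq2 (adjusted p = 0.170) and without wounded replicate 2 (adjusted p = 0.314 by edgeR's test). The 8 largest rises under the rule for named genes were long genes (Galntl6, Dgkb, Grm7, Spag16, Anks1b, Ptprn2, Adgrb3 and Sox2ot), with 0.914 to 2.49 observed over length-expected. Of 3962 genes 1821 changed, 798 up and 1023 down, against 1633 up and 1050 down with DESeq2, 854 up and 583 down with the length trend removed, and 1084, 1203 and 439 genes without unwounded replicate 1, unwounded replicate 2 and wounded replicate 2. Sebocyte-like nuclei (joint cluster 11, wounded cluster 14) showed a fall of Sdr16c6, a retinol dehydrogenase, which went from 1150 ± 69.2 CPM to no count, at least 21.6-fold lower. Their largest rises included Trem3, from no count to 523 ± 156 CPM with 142 and 83.0 observed over length-expected, and Nrg1, at least 175-fold higher with 2.39 and 1.86. In them 1065 of 3259 genes changed, 552 up and 513 down, against 545 up and 307 down with the length trend removed, 215 up and 411 down after subtraction, and 702 and 307 genes without unwounded replicate 1 and wounded replicate 2. None of 20 lists passed there in camera, with 1 list passing after subtraction or without wounded replicate 1 or 2.

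Among the 18 wounded clusters with at least 10000 UMIs in both libraries, some wound genes lay mainly in named clusters and others did not. Krt16 reached 719 and 732 CPM in the keratinocyte-like cluster 5 and at most 94.4 and 139 CPM elsewhere. Krt6a (3 and 12 UMIs) and Krt6b (4 and 12 UMIs) were also highest there. Il33 was highest in the fibroblast-like clusters 3 (613 and 332 CPM) and 9 (592 and 167 CPM), against 291 and 108 CPM in cluster 5. Cxcl5 had 129 and 168 CPM (19 and 46 UMIs) in cluster 3 and 188 and 60.8 CPM (7 and 4 UMIs) in cluster 9, against 62.7 and 66.2 CPM in the unnamed cluster 2. Tnfaip6 and Tnc were among the leading genes of cluster 9, with 22126 and 16712 CPM and with 1857 and 1140 CPM, and so helped define it. Cxcl2, Cxcl3 and Spp1 were high in the unnamed clusters 2 (149 and 89.3, 243 and 76.1, and 188 and 109 CPM) and 6 (191 and 80.2, 363 and 104, and 210 and 144 CPM). Csf3r was high in cluster 2 as well, at 267 and 218 CPM (34 and 66 UMIs). Ptgs2 and S100a9 were counted in named and unnamed clusters alike, Ptgs2 at 39.2 and 116 CPM in cluster 2 and 47.7 and 65.6 CPM in cluster 3, and S100a9 at 102 and 39.7 CPM in cluster 2 and 38.8 and 87.4 CPM in cluster 5. Trem3 was highest in the unnamed cluster 12 and was counted in every wounded cluster, so its rises within types are not assigned to them. These levels were not tested between clusters, since each rests on 2 libraries. Malat1 within types fell as in all nuclei, from 10.6% and 10.5% to 0.708% and 1.03% of UMIs in fibroblast-like and from 6.52% and 5.91% to 0.284% and 0.364% in keratinocyte-like nuclei.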

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

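The tests of depth, of the mix of cell types and of dilution by genomic DNA alone for Malat1, of genomic DNA alone for the inflammatory genes, of dilution for the dermal genes, and of the difference between keratinocyte and fibroblast clusters were chosen only after the result was seen, as was the unwounded control of the X-linked genes.

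Inflammatory and neutrophil genes were counted in barcodes that the all-nuclei comparison left out. With a limit of 100 genes, 4621 of 4635 and 16075 of 18026 wounded barcodes passed the filters before doublet removal. Most barcodes under 200 genes thus met the limit of the comparisons within cell types. The 2250 and 13696 wounded barcodes with fewer than 200 genes carried 422 and 2028 UMIs of the 32 genes of these lists, or 1021 and 1003 CPM. The wounded barcodes above that limit had 515 and 665 CPM, and the unwounded ones 140 and 128 CPM. In unwounded skin only 1 and 69 barcodes were left out, with 0 and 189 CPM.

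Some genes changed by different amounts in keratinocyte-like and fibroblast-like clusters. In the test of the difference itself, 852 of 9371 genes passed, 287 with a higher and 565 with a lower log2 fold change in keratinocyte-like nuclei, and 1894 had an unadjusted p under 0.05. Sod2, a mitochondrial superoxide dismutase induced by NF-kappaB, had a difference of -2.54 ± 0.52 (SE; adjusted p = 5.46e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Il33 of -1.90 ± 0.63 (adjusted p = 0.0333) and Nfkbia of -1.72 ± 0.60 (adjusted p = 0.0494). These 3 were chosen from the fixed lists after their values were seen. The genes of smallest p included Skint5, Dab1 and Skint6, with differences of -5.09, -4.78 and -4.15. They were also among the leading genes of the unwounded keratinocyte cluster 7. Such differences could arise if wounded counts of both types came in part from background, which was not tested. The 852 genes are therefore not read as a difference of wound response alone. The balance of the directions was not stable, with 424 higher and 278 lower without wounded replicate 1 and 328 higher and 257 lower without unwounded replicate 2. The count was 263 without unwounded replicate 1, 226 without wounded replicate 2 and 385 after subtraction of the length-expected counts. Sod2 within fibroblast-like nuclei rose by a log2 fold change of 1.41 ± 0.28, which was 0.27 without wounded replicate 2.

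The first pattern was the low Malat1 share of the wounded libraries, at most 0.294% of UMIs against at least 8.26%. Lower depth was not decided by the gene limit. Wounded barcodes with at least 400 genes reached at most 0.194%. The wounded share fell as the limit rose, however, from 0.177% and 0.351% at 100 genes. The wounded cluster of highest median UMIs (434) held 0.0274% Malat1 and 0.637 and 0.602 receptor CPM per kilobase. A high gene count may thus mark background instead of RNA. Another mix of cell types is argued against, as within each of 4 named types the unwounded share was at least 4.44 times the wounded one. Dilution by genomic DNA alone is argued against as well, since Malat1 would be at most 0.803% of the counts left after the length-expected background. A contribution from genomic DNA met both bounds set beforehand. The receptor genes lay at least 49.3 times higher in wounded libraries, at 0.669 and 0.631 of the density of autosomal genes. The length-expected background came to 68.4% and 63.4% of wounded UMIs. The CPM per kilobase of nearly silent X-linked over autosomal genes (0.403 and 0.398 wounded, 0.578 and 0.634 unwounded) lay in the range set for a single X chromosome in both groups, so it decides nothing, and the sex of the mice is not given in the sources used here. Loss of RNA from damaged nuclei and an effect of wounding on Malat1 itself were not tested and stay open.

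The second pattern was the high level of inflammatory and neutrophil transcripts, 18 members of both lists having risen. Counts freed by the fall of abundant genes are argued against, because without the 50 most abundant genes the median log2 fold change was 4.80. Genomic DNA alone is argued against for the set, because 8 of the 18 lay above the 99th percentile of nearly silent genes in both wounded libraries. That percentile came from genes of at least 5 kb, whereas the measured inflammatory members had a median length of 3.06 kb. The spread of the ratio among shorter genes was not measured, and the 18 were taken because they were called as rising. For the members as a whole a share from genomic DNA and expression cannot be told apart, since their median observed over length-expected was 4.18 and 7.79, between the bounds set beforehand, and members such as Mmp8 lay at 1.52 and 1.74. Entry of leukocytes and induction in resident cells both stay open as hypotheses for the 8 and may both apply.

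The third pattern was the fall of 14 dermal matrix transcripts. Dilution by counts from genomic DNA is argued against as the whole cause of the fall in their summed level. Their summed CPM of 13139 and 13344 fell to 1015 and 1185, at least 11.1-fold, whereas the background could dilute RNA by 3.17-fold and 2.73-fold. Abundant members weigh most in this sum, with Col1a2 at 4251 and Col1a1 at 3063 CPM in unwounded skin, so it does not speak for each transcript. The 14, taken because they were called as falling, had a median fitted log2 fold change of -3.10 (SD 1.8). Fewer fibroblasts and lower levels within fibroblasts cannot be told apart, because within the fibroblast-like clusters the median log2 fold change was -1.84 (SD 1.60, range -5.33 to -0.01) and these clusters came from 2 clusterings. Loss of dermis from the sampled wound, loss of RNA and lower transcription were not tested and stay open.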

How the results depend on the processing

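Removal of the length trend, subtraction of length-expected counts, barcodes with a Malat1 UMI, and all tests on separately clustered nuclei were chosen after seeing the data. Of the values under alternatives for single genes, lists and classes, 3022 kept direction and side of the threshold, 132 lost the call, 13 gained it, 27 moved and 26 turned. Of the counts that answer a comparison, 106 stayed within 1.5 times and 35 did not. The causes of shifts were not tested, except that fewer genes entered the fits after thinning and more without the filter. All-nuclei counts lay between 12528 (subtraction) and 22204 (no filter), with 5021 falls after thinning and 5073 rises after subtraction. Of the genes called after subtraction, 11515 were shared with the main test and 11235 had the same direction. The replicate numbers did not pair the mice (correlation of deviations 0.0434 over 2 pairs). With the replicate number as a block 17579 genes and 16 lists were called, the added list being mitochondrial transcripts (adjusted p = 0.0338).

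Turned values were as follows. With the length trend removed, log2 fold changes were -0.0017 for Oasl2, -0.10 for Diaph3, 0.40 for mt-Co3, 0.15 for mt-Atp6, 0.31 for mt-Nd1, 0.62 for Hba-a2 and 0.62 for Scd1 in sebocyte-like nuclei. After subtraction they were -7.89 for Lamb3, 0.0591 for Stat2, -10.41 for Diaph3 (-0.52 in fibroblast-like nuclei) and 0.0071 for mt-Nd1. That step set wounded counts below the length-expected level to 0, so large negative values are not measured falls. Hba-a2 had 0.0098 with at least 100 genes and 0.34 with all barcodes. Lists that turned did so without passing: fry gave adjusted p = 0.875 for epidermal differentiation and 0.0616 for matrix remodelling. With a library left out, matrix remodelling ranged from 0.567 to 0.968 in camera and turned only without wounded replicate 1 (0.968). It also turned after subtraction (0.453) and in barcodes with a Malat1 UMI (0.856). Cell cycle had 0.987 without the length trend, basal keratinocyte 0.952 after subtraction, and mitochondrial transcripts 0.254, 0.322 and 0.811 without the length trend, after subtraction and in barcodes with a Malat1 UMI.

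The 15 lists became 0 with an estimated correlation, 9 after thinning, 7 after subtraction and 8 to 15 with a library left out. Class shares passed in 9 of 9 classes and in 2 with TMM factors, where log2 changes of adipocyte and sebocyte shares turned to 0.628 and 0.633. With at least 100 genes 1 class could be tested. Its 747 muscle genes became 1443 with DESeq2, 1805 without the filter, 116 after thinning and 0 to 717 with a library left out. For separate clusters, the counts without the filter, after thinning and over left-out libraries were 5242, 576 and 1073 to 2254 for keratinocyte-like, 13644, 2798 and 5207 to 7922 for fibroblast-like, 3654, 189 and 439 to 1311 for muscle-like and 2598, 72 and 307 to 919 for sebocyte-like nuclei, the last also 1970 with DESeq2 and 626 after subtraction. Genes differing between keratinocyte-like and fibroblast-like nuclei numbered 385 after subtraction and 226 to 702 with a library left out. In the wounded libraries 3 counts equal 2.52 and 2.22 CPM.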

Other observations

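The test of mt-Co1 between clusters was chosen after seeing the data, like all others on separate clusters. In fibroblast-like nuclei some glycolytic and mitochondrial genes rose. Of 13 glycolysis genes 5 rose, 1 fell and 7 did not pass, and the list passed after subtraction (adjusted p = 0.0484, against 0.223 in the main test and 0.769 with an estimated correlation). Of 12 mitochondrial transcripts 8 rose and none fell. The glycolytic regulator Pfkfb3 rose from 19.8 ± 0.453 to 121 ± 11.3 CPM, a log2 fold change of 2.17 ± 0.29, with 5.97 and 4.70 observed over length-expected, and the glycolytic enzyme Gapdh from 7.48 ± 3.92 to 38.0 ± 25.9 CPM (18.0 and 35.7). The cytochrome oxidase subunit mt-Co1, transcribed in mitochondria, rose from 40.8 ± 8.91 to 159 ± 50.8 CPM, a log2 fold change of 1.58 ± 0.26. Its change was 1.53 log2 units smaller in keratinocyte-like nuclei (-1.53 ± 0.47, adjusted p = 0.0179 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The interferon-induced Oasl2 rose from 15.5 ± 1.23 to 146 ± 37.1 CPM in fibroblast-like and from 6.81 ± 5.16 to 75.8 ± 2.66 CPM in keratinocyte-like nuclei, with observed over length-expected of 49.1 and 23.6 and of 19.0 and 13.4. Its list did not rise in fibroblast-like nuclei, with 2 of 10 members up, 2 down and 6 not passing (adjusted p = 0.672).

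Trem3, a receptor of myeloid cells, went from no count to 266 ± 119 CPM in keratinocyte-like, 314 ± 35.8 CPM in fibroblast-like and 523 ± 156 CPM in sebocyte-like nuclei. It was counted in every wounded cluster and was highest in the unnamed cluster 12, at 5458 and 3361 CPM, so its rise was not specific to these types. Csf3r, a receptor of neutrophil precursors and neutrophils, rose from 7.36 ± 3.01 to 79.2 ± 2.09 CPM in keratinocyte-like and from 2.97 ± 1.13 to 90.8 ± 24.2 CPM in fibroblast-like nuclei. It was higher in the unnamed wounded cluster 2, at 267 and 218 CPM, and reached 77.2 ± 0.261 CPM over all wounded nuclei, so it is not assigned to these types either.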
